A study of Homo sapiens with 3 samples.

How the data were processed

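RWPE1 cells, an established benign prostate epithelial line, were infected with a retrovirus carrying the empty vector, MYC or a constitutively active PI3K mutant (E545K), per the labels. The labels give 1 Illumina array per group, so 3 arrays were analysed, with no replicates. Per the labels' protocols, RNA was extracted with Trizol, cleaned on RNeasy columns with DNase I treatment and labelled as biotinylated cRNA with the MessageAmp kit. GenomeStudio is named in the submitters' processing notes, and its version is not given in the sources used here.

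Both deposited tables cover 24526 probes. The scanner table holds linear signal intensity values deposited without normalisation, per the file headers. Beside each signal the authors deposited a detection value, named as a detection p-value in the header. Its values run the other way: they rank with the signal (rank correlation 0.976 on the vector array and 0.981 on the array labelled MYC), so each was read as 1 minus the detection p-value. Signals and detection values were used for the vector array and the array labelled MYC. The table has 2 more columns of per-sample values that name no sample of the series, and these were not used.

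The authors' second table holds log2 values for all 3 arrays. Set against the scanner table, its MYC minus vector difference equalled the log2 ratio of the signals plus a constant of 0.52, which is the log2 ratio of the arrays' 75th percentiles (563.5 for the vector array and 393.8 for the array labelled MYC). For these 2 arrays the deposited log2 values therefore differ as signals scaled to the 75th percentile do. A constant was taken from each probe, and its origin stays unknown. The columns used here do not allow this check for the PI3K column, which was assumed to be made in the same way. Column medians are -0.16 for the vector array, 0.07 for the array labelled MYC and 0.04 for the PI3K array.

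The signal of the PI3K array was rebuilt as the vector signal multiplied by 2 to the power of the deposited PI3K minus vector log2 difference. This puts it on the vector array's scale, and the array labelled MYC was placed on the same scale in the same way. The plan had been limma's neqc on all 3 arrays, which needs detection p-values on each. With no usable ones for the PI3K array, the plan's stated fallback became the main setting: limma's normexp background correction with an offset of 50, quantile normalisation over the 3 arrays and log2. A probe counted as above background on the vector array or the array labelled MYC at a detection p-value under 0.01. On the PI3K array it counted at a scaled signal of at least 283.7, the higher of the scaled cut-offs of the other arrays, and the vector array's own cut-off was 233.3. The detection calls, counts and bounds of the PI3K array therefore rest on this substitute. This passed 9700 probes on the vector array (39.5%), 9097 on the array labelled MYC (37.1%) and 9107 on the PI3K array (37.1%).

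Of the probes, 21834 have 1 gene symbol in the platform annotation, 0 have several and 2692 are unnamed here. Symbols were matched by gene ID to a reference table of current symbols, which held 21813 of them, and they cover 16922 genes. No genome coordinates are printed, because no build is named for the array. A gene took the value of its brightest probe (mean over the arrays) among those above background on at least 1 array, which left 8270 genes.

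Comparisons are log2 differences between 2 arrays, over genes above background on at least 1 of them. There is no test, p-value or standard error, because each group is 1 array. Genes at least 2-fold apart were counted. For a gene above background on 1 array only, the fold is a lower bound: its normalised signal over the higher of the dim array's lowest above-background signal and the probe's own. Counts are also given with such genes at their bound. The error available is technical: for 719 genes with 2 or more probes above background on all arrays, the SD between a pair of probes in the log2 difference, divided by the square root of 2, was 0.21 for both comparisons with the vector and 0.19 for the third. This leaves out the differences between cultures, hybridisations and RNA preparations. A 2-fold call can also depend on the probe. For the array labelled MYC against the vector, the brighter probe passed 2-fold in 35 of these genes. The second probe had the same sign in 34 and passed 2-fold in 18. The PI3K array against the vector gave 20, 20 and 11, and the third comparison 30, 30 and 20.

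Before the data were examined, 38 gene lists (pathways, cell types, controls) were fixed from general knowledge. A list with at least 3 measured members is described by its median difference and that median's percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. A percentile under 2.5 or over 97.5 is called apart from matched lists, as a description of these arrays. Named genes also follow a rule fixed then. For each comparison with the vector it takes the 10 highest and 10 lowest differences among genes above background on both arrays, the 3 largest bounds each way, and every MYC and PIK3CA probe. For the array labelled MYC against the PI3K array it takes the 5 highest and 5 lowest. For each list described it takes up to 4 members with the largest differences, which were not picked by any test. Uncharacterised loci and small RNA genes were counted and not named. Of the genes given by the rule, 1 is not reported here.

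The steps were tested on simulated arrays for the array labelled MYC against the vector, with 8112 genes in the step and noise of 0.2 log2. Of 3-fold changes, 92% of the higher and 84% of the lower passed the 2-fold threshold, and of 4-fold changes 100% and 96%. Of 7884 unchanged genes, 2 passed it, and 5% of 200 unchanged lists were called apart. These rates hold for that noise only, and the overlap simulation below had a median noise of 0.28 log2. Noise was drawn for each probe separately, so the list rate leaves out genes that vary together. Of 36 lists measured, 9 were apart higher and 10 lower for the array labelled MYC against the vector. The counts were 9 and 9 for the PI3K array against the vector, and 8 and 8 for the third comparison. Alternatives changed the background correction, the scaling (median, cyclic loess, the authors' values), the detection rule, the choice of probe and the fold threshold. Added after the data were seen were neqc on the vector array and the array labelled MYC alone and the vector cut-off on the PI3K array. Counts without the members of the interferon, antigen presentation and inflammatory lists were also added then. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.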

Results

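Gene expression was measured in RWPE1 cells, a benign human prostate epithelial line, carrying an empty retroviral vector, MYC or the active PI3K mutant E545K. Each group had 1 array, so no difference below has a replicate check. Median signal was 158.9 on the vector array and 128.7 on the array labelled MYC, before scaling. Above background on the vector, MYC-labelled and PI3K arrays were 7899, 7393 and 7434 genes. Across the 8270 genes measured, the PI3K array correlated with the MYC-labelled array at r = 0.950 and with the vector array at r = 0.946, and the MYC-labelled and vector arrays correlated at r = 0.920. Genes are not independent replicates, so these values describe the arrays only.

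The introduced genes were examined first. MYC is read by 1 probe, whose signal was 6229 on the vector array and 3655 on the array labelled MYC before scaling. After normalisation its log2 signal was 12.62 on the vector array, 12.35 on the array labelled MYC and 11.80 on the PI3K array, so the difference of the array labelled MYC from the vector was -0.26. The MYC probe therefore goes against the label in showing no rise, while a drop of -0.26 is near the technical error of 0.21. Where it lies relative to the introduced coding sequence is not known here, and a probe outside that sequence would check nothing. For this reason the text speaks of the array labelled MYC throughout, and each direction drawn from it rests on the label. PIK3CA is named for 0 probes, so the PI3K array has no such check.

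The first comparison asks how cells labelled as overexpressing MYC differ from vector cells. Interferon-stimulated genes were far lower on the array labelled MYC: all 35 measured members of the interferon response list were at least 2-fold lower, with a median log2 difference of -3.45. MX1, an antiviral GTPase, was at least 109.6-fold lower, IFI27 at least 66.3-fold and the RNA-sensing synthetase OAS2 at least 29.5-fold by its brightest probe. The 2 other OAS2 probes fell short of that bound, and the smaller of their drops was a log2 difference of -3.00. Genes of ribosome production, protein synthesis and cholesterol synthesis were higher as groups, by smaller amounts. The gelatinase MMP9 (16.6-fold) and the neuropeptide precursor GAL (8.82-fold) had the highest differences from the vector among genes above background on both arrays. In all, 172 of 8147 genes were at least 2-fold higher and 443 lower, or 143 and 312 with genes below background on 1 array taken at their bound.

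The other genes with the highest differences were the trypsinogen PRSS3 at 2.76, the receptor NOTCH3 at 2.45, the prolyl isomerase FKBP11 at 2.41, NT5DC2 at 2.19, APCDD1L at 2.11, the cytokine receptor subunit IL27RA at 2.01, the Mediator subunit MED24 at 1.99 and the aminopeptidase ANPEP at 1.93. A second MED24 probe gave 2.06. PRSS3 belongs to a family of similar trypsinogens that 1 probe may not separate. Not above background on the vector array were INHBE, at least 4.27-fold higher, TNFRSF8, at least 3.66-fold, and SUN3, at least 3.53-fold.

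Of the 10 lowest genes above background on both arrays, 6 are interferon-stimulated: IFIT1 at -5.11, the ISG15 ligase HERC5 at -4.82, OASL at -4.25, the ubiquitin-like modifier ISG15 at -4.15, the transcription factor subunit IRF9 at -3.77 and IFITM1 at -3.45. A second OASL probe gave -2.77. The others were the kinase SGK1 at -4.24, the matricellular protein CCN2 at -4.11, the fibulin EFEMP1 at -3.75 and the tight junction protein CLDN1 at -3.73.

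Immune genes beyond the interferon list were lower too. MHC class I presentation had a median of -0.83, with 11 of 11 measured members below 0 and 3 at least 2-fold lower, among them the immunoproteasome subunits PSMB9 (-3.08) and PSMB8 (-1.36) and the peptide transporter TAP1 (-1.61). HLA genes in this list share sequence, and their probes may read more than 1 of them. Inflammatory cytokines and NF-kB targets had a median of -0.85 (-0.60 with bounds and -0.42 over the 14 above background on both arrays), with 10 of 23 members at least 2-fold lower (9 with bounds) and 1 higher. The chemokine CCL5 was at least 4.64-fold lower, CCL2 at least 2.86-fold, the complement factor CFB at least 5.07-fold, and the acute-phase protein SAA1 gave -3.06.

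Growth and synthesis genes were higher. The MYC growth targets, a list of nucleolar and metabolic genes, had a median of 0.55 (percentile 100), with 37 of 40 members above 0 but only 4 at least 2-fold higher: FARSA at 1.29, NOLC1 at 1.16, RRP12 at 1.09 and MYBBP1A at 1.03. Ribosome biogenesis and RNA polymerase I genes had a median of 0.54, with 28 of 29 members above 0, the highest being BOP1 at 1.03. Polyamine and nucleotide synthesis had a median of 0.37, with CAD, which starts pyrimidine synthesis, at 1.27 and ODC1, the rate-limiting enzyme of polyamine synthesis, at 1.18. Aminoacyl-tRNA synthetases had a median of 0.34 and 0 members 2-fold apart, led by LARS1 at 0.62. This list leaves out the synthetase subunit FARSA, which is counted with the MYC growth targets above (1.29). Cholesterol synthesis had a median of 0.54, with 15 of 15 members above 0 and 4 at least 2-fold higher (3 with bounds), including DHCR7 at 1.28 and HMGCS1 at 1.27. Fatty acid synthesis had a median of 0.39, with the fatty acid synthase FASN at 1.49. Cytosolic ribosomal proteins had a median of 0.15, a shift that 3 of 9 alternatives did not place apart, and copies of these genes make single members uncertain.

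Mitosis genes lay lower, with a median of -0.48 and 33 of 37 members below 0, though only KIF20A (-1.30) passed 2-fold. DNA replication genes had a median of 0.05, not apart from matched lists. Among epithelial lists, basal markers had a median of -0.29 with 5 of 16 members at least 2-fold lower: KRT15 was at least 8.27-fold lower, KRT14 gave -2.11, KRT5 -1.72 and CAV2 -1.35. Keratin paralogs are similar in sequence, which limits single keratins. Squamous differentiation had a median of -1.16, which depended on dim genes: it was -0.51 with bounds and -0.07 over the 9 members above background on both arrays, where it was no longer apart from matched lists. With no detection filter it was not apart either. Of the luminal prostate markers 8 of 23 on the array were measured, with a median of -0.77 (percentile 0.06, or -0.0335 and no longer apart with no detection filter), KRT19 at -2.62 and SLC45A3 at least 1.70-fold higher. Of the WNT and NOTCH genes, 5 of 15 were at least 2-fold lower and 1 at least 2-fold higher, with DKK3 at -2.47, DLL1 at least 2.55-fold lower and NOTCH3 higher as above.

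Markers of other cell types were scarce. Endothelial markers had 0 measured members, neuroendocrine markers 1 (UCHL1, at least 2.05-fold higher on the array labelled MYC), and leukocyte markers 4, with a median of -0.05. Housekeeping genes had a median of -0.03. Each value rests on 1 array per group, so a shift of a list is a description of this pair of arrays.

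The second comparison asks how cells carrying active PI3K differ from vector cells. Interferon-stimulated genes were again lower, with a median of -2.20 and 32 of 35 measured members at least 2-fold lower: IFI27 gave -4.23, XAF1 -3.85 and MX2 -3.51. Cholesterol synthesis was higher, with a median of 0.92, and so were fatty acid synthesis, glycolysis and mitosis genes. WNT and NOTCH genes and genes that FOXO factors activate were lower. In all, 89 of 8136 genes were at least 2-fold higher and 358 lower, or 80 and 269 with dim genes at their bound.

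The metallothionein MT1G, a metal-binding protein, had the highest difference at 2.59 (6.01-fold), and its probe may also read other metallothioneins. Next came the transporter SLCO4A1 at 2.05, the phosphatidylinositol transfer protein PITPNC1 at 2.04, the scaffold AKAP12 at 2.02, HMGCS1 at 1.75, PHACTR3 at 1.73, MMP9 at 1.70, the chromatin protein HMGA2 at 1.64, ERVMER34-1 at 1.60 and the cytidine deaminase CDA at 1.59. The second AKAP12 probe gave only 0.07, so that gene's probes disagree, while those of PITPNC1 (1.34), PHACTR3 (1.41) and HMGA2 (0.79) went the same way. Bounds on genes not above background on the vector array were at least 3.03-fold for MVD, 2.73-fold for FUOM and 2.71-fold for SCG5.

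Among the lowest genes above background on both arrays, IFI27, XAF1, MX2, OAS2 (-3.33), EPSTI1 (-3.21) and MX1 (-2.91) belong to the interferon list. The remaining lowest genes were CLDN1 at -3.30, PLAAT4 at -3.21, the lysosomal protein LAMP3 at -2.86 and SNRPN, an imprinted gene for a splicing protein, at -2.84. Not above background on the PI3K array were IFI44L, at least 16.6-fold lower, RSAD2, at least 11.3-fold, and the kallikrein KLK5, at least 13.3-fold. Other KLK5 probes gave -0.92 and -4.04.

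Cholesterol synthesis had the highest median of all lists. Of 16 measured cholesterol synthesis genes, 15 were above 0 and 6 at least 2-fold higher, with HMGCS1 at 1.75, IDI1 at 1.51, SQLE at 1.41 and MVD as above. Fatty acid synthesis had a median of 0.35 and 4 of 15 genes at least 2-fold higher: ACLY at 1.55, FASN, which was 2.82-fold higher, ACSS2 at 1.26 and SCD at 1.15. A second ACSS2 probe gave 0.53. Glycolysis had a median of 0.44 with 19 of 20 members above 0, among them ALDOC at 1.47 and the glucose transporter SLC2A3 at 1.39. Mitosis genes had a median of 0.42 with 37 of 39 members above 0 and 0 past 2-fold, led by KIF11 at 0.96. DNA replication had a median of 0.25, polyamine and nucleotide synthesis 0.42, with ODC1 at 1.04, and heat shock and chaperone genes 0.40, with the co-chaperone STIP1 at 1.13. Heat shock and chaperone genes were apart on the array labelled MYC too, with a median of 0.32 (percentile 99.79). Between that array and the PI3K array they were not apart (median -0.14, percentile 6.58). MYC growth targets had a median of 0.17 (percentile 95.7), not apart from matched lists, though 5 of 9 alternatives placed it apart, with medians up to 0.22. Ribosome biogenesis and RNA polymerase I genes were apart on the PI3K array too, with a median of 0.24 (percentile 99.54) and 22 of 29 members above 0. They stayed apart under every alternative.

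FOXO-activated genes, which PI3K signalling represses, had a median of -0.51 (percentile 0.01) with 5 of 18 at least 2-fold lower (4 with bounds). These were TNFSF10 at -2.69, which interferon also induces, PDK4 at least 1.72-fold lower, FBXO32 at -1.59, BCL6 at -1.32 and IRS2 at -1.20. A second FBXO32 probe gave -0.33, and the list's median was -0.22 over the 15 members above background on both arrays. On the array labelled MYC the list had a median of -0.21, not apart from matched lists, but 6 of 19 members were at least 2-fold lower there (5 with bounds), and these include all 5 lower on the PI3K array. Of 14 WNT and NOTCH genes, 8 were at least 2-fold lower, or 6 with bounds (median -1.14, or -0.60 with bounds), including SFRP1 at -1.86, NOTCH1 at -1.69 and DLL1, at least 2.55-fold. Antioxidant and detoxification genes had a median of -0.26, with AKR1B10 at least 2.34-fold lower, ALDH3A1 at -2.27 and AKR1C2 at -1.71. On the array labelled MYC this list had a median of -0.25 (percentile 2.71), not apart, though 3 of 9 alternatives placed it apart. There 4 of 18 members were at least 2-fold lower and 1 higher, with ALDH3A1 at -2.25. Lower by this threshold on both arrays were 4 members. AKR1C copies are near-identical, so their probes may not separate them. Among TGF-beta and BMP targets (median -0.28, or -0.12 with no detection filter) ID1 gave -2.04 and ID3 -1.44. Of the 11 measured, 2 were at least 2-fold lower and 1 at least 2-fold higher. ATF4 and amino acid response genes had a median of -0.30 (-0.16 with the authors' values), with NUPR1 at -1.82.

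Basal markers had a median of -0.30, with KRT15 at -2.26, KRT14 at -1.02, the protease inhibitor SLPI at -0.94 and the integrin ITGA6 2.01-fold higher. Squamous differentiation had a median of -0.43, with 5 of 15 members at least 2-fold lower (4 with bounds), among them CALML3 at -1.69 and KLF4 at -1.52. With no detection filter this median was -0.0538 (percentile 4.65) and no longer apart. MHC class I presentation was lower, with a median of -0.48 and 2 of 11 members at least 2-fold lower, TAP1 at -1.48 and PSMB9 at -1.25. Inflammatory genes had a median of -0.10, not apart, though 6 of 23 were at least 2-fold lower, including CCL2, at least 2.87-fold. Leukocyte markers had 6 measured members and a median of 0.53 (0.22 with bounds), and of these the actin-bundling protein LCP1 was at least 2.41-fold higher. Over the 3 of them above background on both arrays the median was 0.26 and no longer apart from matched lists. These values share the limits of the first comparison: 1 array per group and, for a single gene, a technical error of 0.21.

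**Figure D1:**
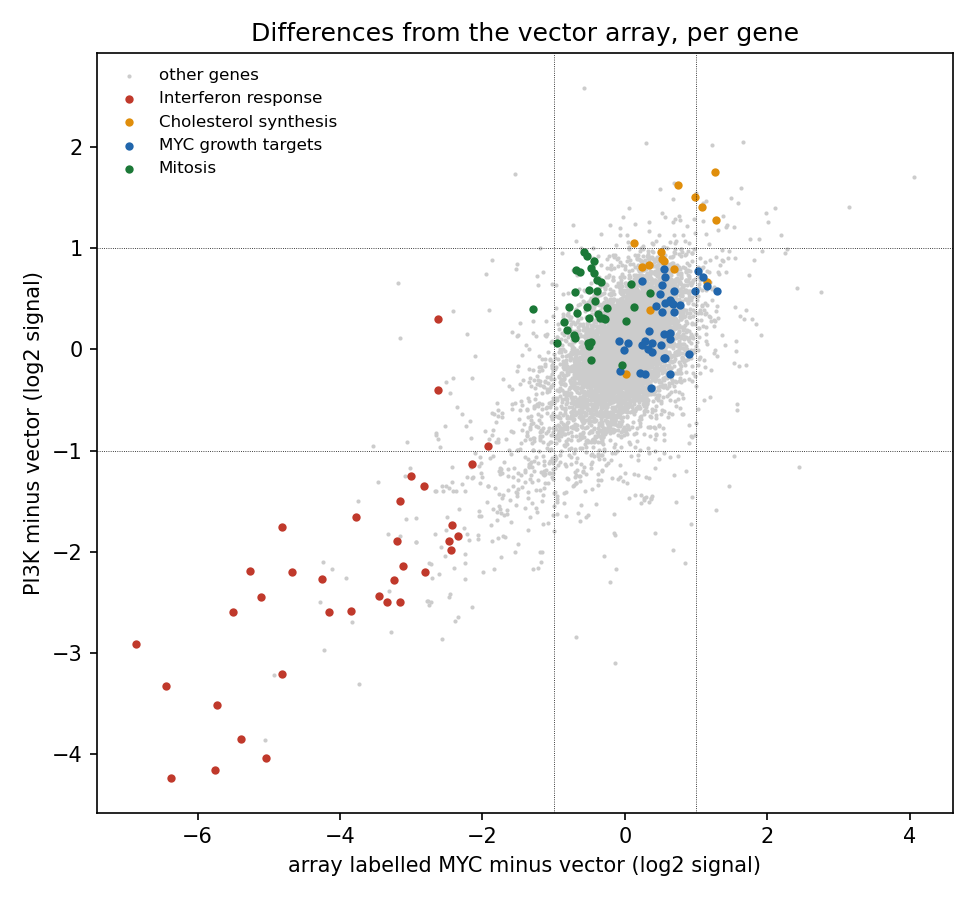
Each point is a gene above background on the vector array or on both others, placed by its log2 difference from the vector on the array labelled MYC (x axis) and on the PI3K array (y axis), with 4 gene lists in colour and dotted lines at 2-fold. Interferon genes lie at the lower left, with medians of -3.45 and -2.20, and mitosis genes lie left of 0 and above it, with medians of -0.48 and 0.42.

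The third comparison sets the array labelled MYC against the PI3K array. Mitosis genes were lower on the array labelled MYC, with a median of -0.94 and 18 of 39 members at least 2-fold lower: KIF20A gave -1.70, KIF11 -1.53, the cyclin CCNB1 -1.48 and DLGAP5 -1.45. Interferon genes were lower by a median of -1.66, with 23 of 29 at least 2-fold lower, or 19 with bounds. MX1 was at least 14.5-fold lower and IFI44 at least 4.19-fold. In all, 193 of 7805 genes were at least 2-fold higher and 236 lower, or 148 and 172 with dim genes at their bound.

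Among the highest differences were the potassium channel subunit KCNG1 at 2.40, MMP9 at 2.35, the phospholipid transfer protein PLTP at 2.23 and PRSS3 at 2.19. A second PLTP probe gave 1.08. The lowest were FGFBP1, a carrier of fibroblast growth factors, at -3.85, the activin antagonist FST at -3.26, MT1G at -3.17, HERC5 at -3.06 and IFI6 at -2.93. Second probes gave -1.87 for FST and -1.39 for IFI6.

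ATF4 and amino acid response genes were higher on the array labelled MYC (median 0.48, with 23 of 26 above 0), among them NUPR1 at 1.66, the cystathionine lyase CTH, at least 3.04-fold, ATF3 at 1.14 and the serine synthesis enzyme PSPH at 1.09. The unfolded protein response (0.30), aminoacyl-tRNA synthetases (0.30), MYC growth targets (0.28) and ribosome biogenesis (0.28) had smaller positive medians, each apart from matched lists. NOTCH3 was at least 7.84-fold higher on the array labelled MYC. Lower there were cholesterol synthesis (median -0.41, with LSS at -0.92), glycolysis (-0.32, with SLC2A3 at -1.34 and PGK1 at -1.10) and DNA replication (-0.26, with TK1 at -1.38). Housekeeping genes also lay lower, at -0.22 (percentile 1.45, or 2.90 with a gene's probes averaged), which is about the size of the smaller list shifts. FOXO-activated genes had a median of 0.02 between these arrays.

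**Figure D2:**
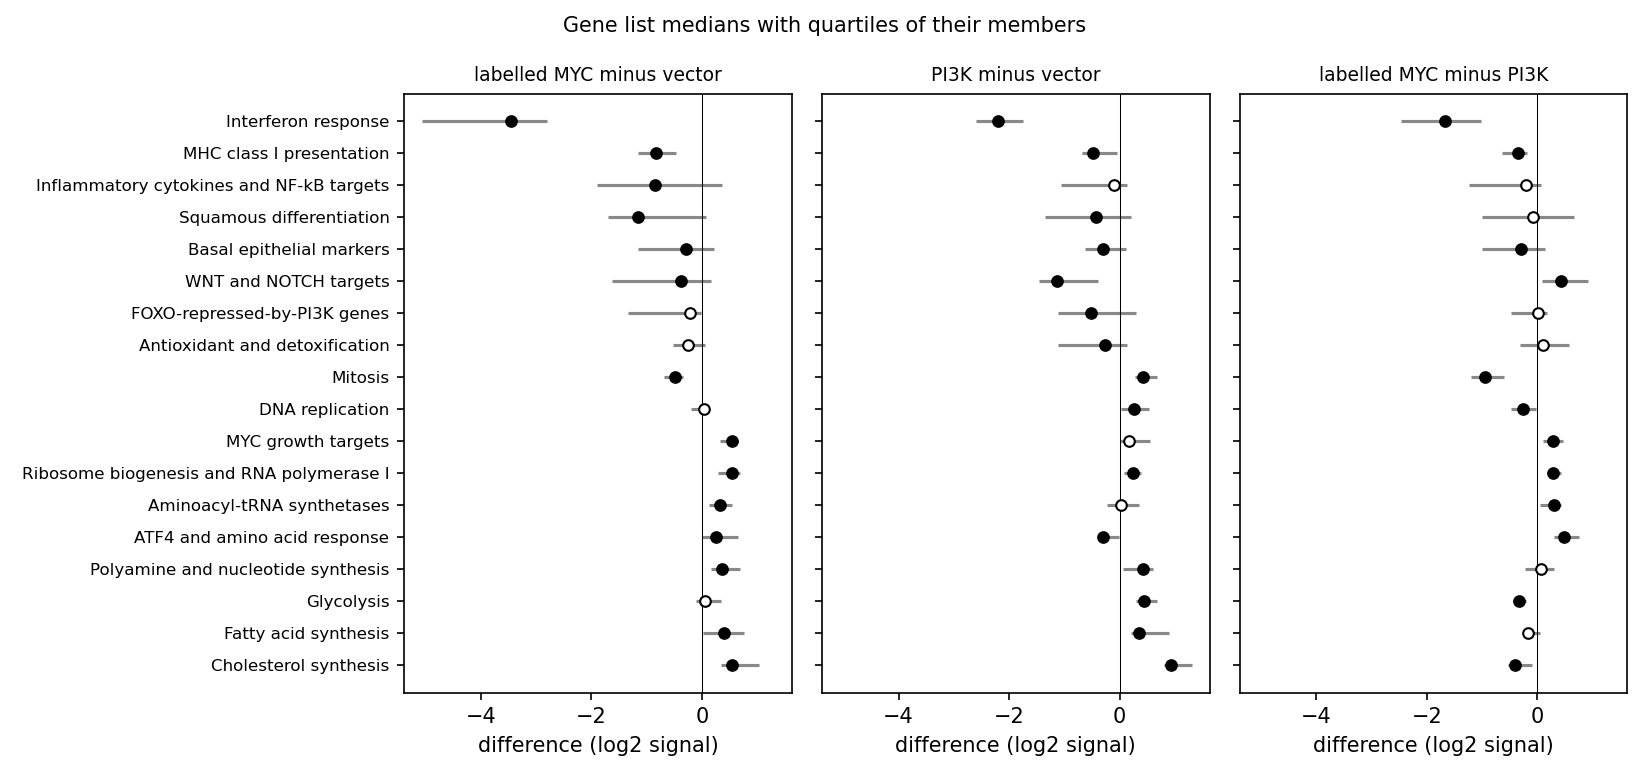
Points are medians of the log2 differences over a list's measured members in each of the 3 comparisons, with lines from the lower to the upper quartile of the members, and filled points are lists apart from matched random lists. The interferon list is lowest in each panel, at -3.45, -2.20 and -1.66.

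The changes from the vector were then compared with each other. Of 8013 genes measured in both comparisons, 225 were at least 2-fold lower on both arrays (87 with only genes above background on the arrays compared) and 26 higher on both, and 6 went opposite ways. Independent lists of these sizes would share 19.8 lower and 1.41 higher genes. Simulated unchanged arrays against 1 shared vector array gave 6.63 and 7.07. Of the genes lower on both, 32 belong to the interferon list, 6 to the inflammatory list and 5 to the FOXO list. Of those higher on both, 3 belong to cholesterol synthesis. Across genes the differences correlated at r = 0.646, against 0.4997 in the simulation, and their covariance was 0.221 against 0.0792. Sharing 1 vector array sets the simulated r near 0.5, and the simulated covariance follows the noise put in (median SD 0.28 log2). Unchanged arrays do not model a vector culture that differs from the others, so the excess over the simulation cannot be assigned to the oncogenes. Both comparisons use the only vector array, which cannot be split, so part or all of the overlap may come from that array.

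**Figure D3:**
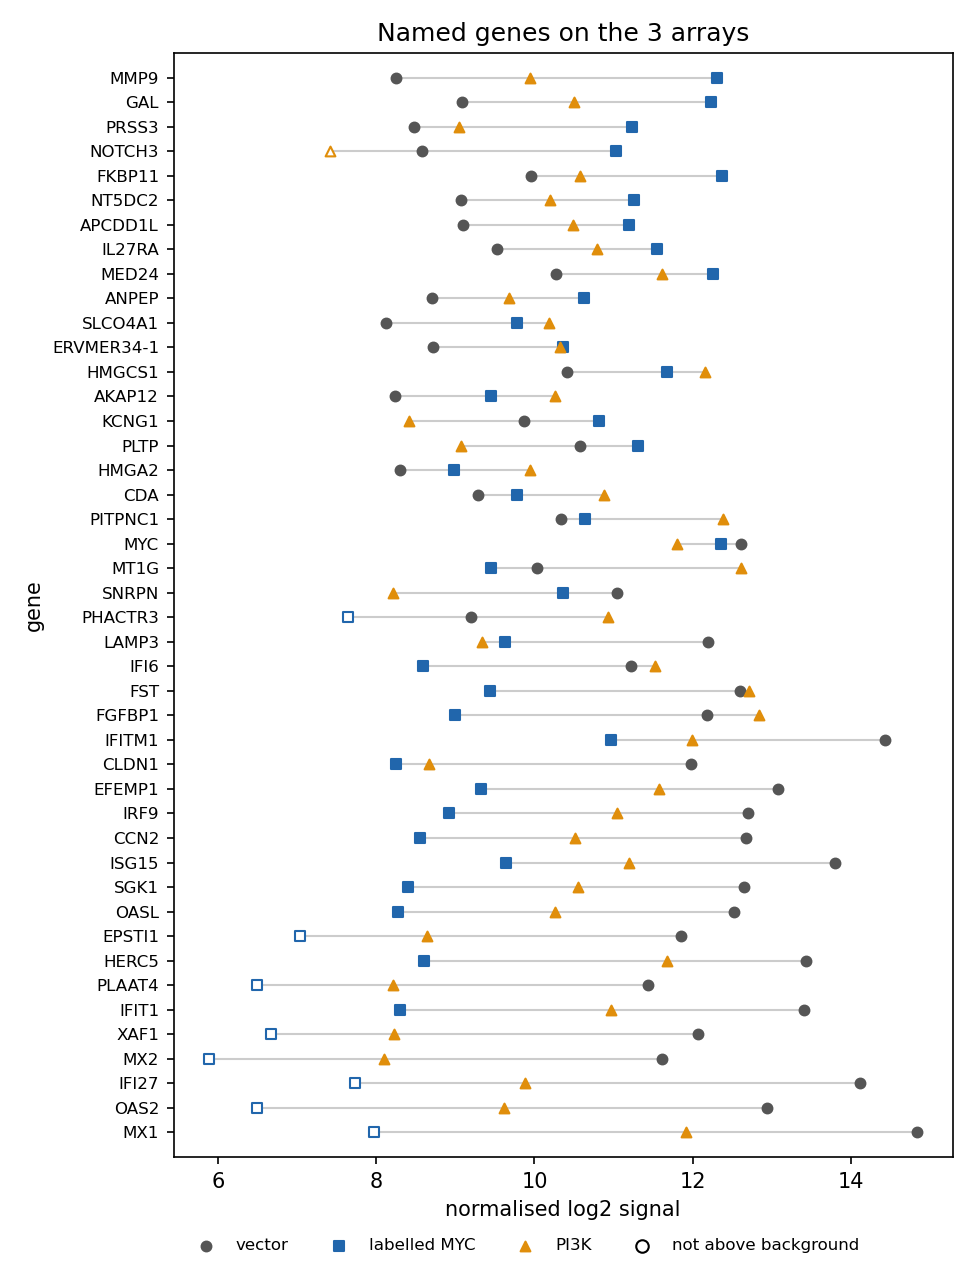
Normalised log2 signal (x axis) on the vector array (circles), the array labelled MYC (squares) and the PI3K array (triangles) is shown for MYC and for genes named by size of difference above, with open symbols where a gene was not above background. MX1 spans the values 14.83, 7.97 and 11.92 on these arrays, and MYC 12.62, 12.35 and 11.80.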

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

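With 1 array per group, no array could be left out, and no paired analysis was possible because the groups share only 1 replicate number and no test was run. The planned normexp setting without detection p-values became the main one and is not an alternative. Under every alternative run, the interferon list stayed apart from matched lists in the 3 comparisons, as did MYC growth targets and cholesterol synthesis against the vector on the array labelled MYC, cholesterol synthesis and the FOXO list on the PI3K array, and mitosis between the MYC-labelled and PI3K arrays. The MYC probe difference ranged from -0.35 (cyclic loess) to -0.25 (the authors' values).

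Counts depended on the treatment of dim genes and on the threshold. With genes above background on both arrays only, fewer genes were lower: 207 on the array labelled MYC and 205 on the PI3K array, with 87 in both. The third comparison then gave 121 higher and 143 lower. At 1.5-fold the counts were 796 higher and 954 lower for the array labelled MYC, 651 and 863 for the PI3K array, 722 and 701 between them, and 217 and 489 in both. At 3-fold they were 35 and 199, 12 and 124, 58 and 72, and 3 and 91. These counts moved through the genes admitted by each rule. With neqc on the vector array and the array labelled MYC, chosen after seeing the data, 310 genes were higher and 594 lower; the cause was not tested. Without the members of the interferon, antigen presentation and inflammatory lists, also chosen then, 171 genes were higher and 395 lower on the array labelled MYC. On the PI3K array they were 89 and 318. Genes outside these fixed lists stayed in, so these counts are not free of other genes that interferon may induce.

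Secreted proteases and inhibitors, higher in the third comparison, changed sign to -0.0842 at a detection p-value under 0.05 and -0.0585 with no detection filter, which admit dimmer genes. Of 970 list medians under alternatives, 908 kept their side of the threshold, 19 lost a call, 34 gained one, 7 others moved by more than the spread between probes and 2 are the sign changes above. Other medians, not apart in the main setting, also crossed 0 and are not in that last count. For the array labelled MYC against the vector, mesenchymal markers ranged from -0.09 to 0.29 and glycolysis from -0.03 to 0.18. Of 571 values of named genes, 540 moved by less than the spread between probes and 0 changed sign past 2-fold. Signal over background limits the dim genes, for which bounds are given, though not for every second probe.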

Other observations

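Of the tests below, those of a vector culture with raised interferon genes, of swapped labels, of a probe for the cell's own MYC transcript and of fewer cycling cells were chosen after the results were seen. Several gene groups remain to be described. SNURF, from the same imprinted locus as SNRPN and so not independent of it, was also lower on the PI3K array. Its log2 signal was 9.44 on the vector array and not above background on the PI3K array, where the lowest above-background signal was 8.06. On the array labelled MYC SNURF gave a log2 difference from the vector of -0.21. The high-mobility group gene HMGA1 was higher on both arrays, at 1.38 on the array labelled MYC and 1.32 on the PI3K array. A second, dimmer HMGA1 probe, not above background on the vector array, gave 0.30 and 0.28. Metallothioneins did not follow MT1G as a family: on the PI3K array MT1E gave 0.76, MT2A 0.21, MT1F -0.16 and MT1X -0.38, and on the array labelled MYC the same genes gave -1.14, -0.55, -1.50 and -1.26. These genes are close copies, and they were chosen after their values were seen. The interferon gene IFNL1, which the fixed rule did not name, was above background on the vector array only. Its log2 signal there was 8.31, near the lowest above-background signal of 8.06 on each of the other arrays, so only a small difference can be claimed.

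Of the remaining lists, p53 targets had medians of -0.04 on the array labelled MYC and -0.15 on the PI3K array, neither apart from matched lists in the main setting, though 2 of 9 alternatives placed the PI3K one apart. Within them the stress cytokine GDF15 was at -1.47 and the repair gene XPC at -1.52 on the PI3K array. The hypoxia list had medians of -0.01 and 0.06, although the vasodilator peptide ADM was at -2.22 on the array labelled MYC and BNIP3 at 1.13 on the PI3K array. On the PI3K array 2 of the 16 measured hypoxia genes were at least 2-fold lower and 1 higher. ERK feedback genes had medians of -0.09 and -0.05, with the transcription factor ETV4 at 1.75 and 1.09. Oxidative phosphorylation had medians of 0.11 and 0.10 and 0 genes past 2-fold on either array. Integrins and adhesion matrix genes were apart on the array labelled MYC, with a median of -0.30 (percentile 0.13) and CCN1 at -1.38, and not on the PI3K array, with a median of -0.11 and THBS1 at 1.07, though 2 of 9 alternatives placed it apart there too.

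The first pattern weighed is the interferon list, lower than the vector on both oncogene arrays. A vector culture with raised interferon genes would lower the list alike on both. The list's median between those arrays was -1.66, below all 10000 matched lists, so this does not account for the further drop on the array labelled MYC. The drop that both share cannot be told apart from such a culture with 1 vector array. The median nearest to 0 over all alternatives and both comparisons was -2.18, which argues against normalisation or background correction as the cause. An effect of each oncogene may account for the pattern, and so may the culture or infection state of the single cultures, which cannot be told apart from it with 1 array per group.

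The second pattern is the MYC probe, lower on the array labelled MYC. If the vector and MYC labels had been swapped, MYC growth targets would be lower there, but their median was 0.55, above all 10000 matched lists. The probe was lower still on the PI3K array, at -0.82 from the vector, so a drop is not particular to the array labelled MYC. On the array labelled MYC the difference was -0.26, near the technical error of 0.21 for a single gene. A candidate explanation for the missing rise is that the probe reads only the cell's own transcript, which introduced MYC could lower. The array has only 1 MYC probe, whose position is not known here, so this stays open, as does a wrong label involving a sample outside the series.

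The third pattern is mitosis genes, lower on the array labelled MYC than on the PI3K array. The list's median nearest to 0 under any alternative was -0.90, which argues against normalisation or background correction. Fewer cells in cycle would lower DNA replication genes too, and their median was -0.26 (percentile 0.09), with 27 of 34 below 0, against -0.94 for mitosis. Against the vector, the array labelled MYC had mitosis genes lower (median -0.48) but not DNA replication genes (0.05, percentile 47.44). The PI3K array had both higher (0.42 and 0.25). The drop from the vector on the array labelled MYC thus did not extend to the replication list. How far each list follows the share of cycling cells is not known here, so fewer cycling cells stay open as an explanation. The oncogenes or culture density may also account for the difference, and with 1 array per group neither was tested.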
